A study of Oncorhynchus mykiss with 69 samples.

How the data were processed

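The study exposed 3 rainbow trout cell lines for 24 h to methylmercury or to fluoxetine and sequenced their RNA in 69 libraries. RTgill-W1 comes from gill, RTL-W1 from liver and RTgutGC (written RTgutCC in the labels) from intestinal epithelium. Per the labels, cells grew in L-15 medium, RNA was extracted with RNeasy columns, and libraries were read as paired ends on a NovaSeq. Methylmercury had 2 libraries for the control and for each of 5 concentrations, so 12 per line. Fluoxetine had 1 library for each of 9 concentrations and 2 controls, named ctrl and H2O, so 11 per line.

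The authors filtered reads with fastp and quantified genes with Salmon, per the labels, which give no versions and no genome build. They deposited 12 tables, a table of fold changes and a table of benchmark doses for each line and chemical, and no table of counts per library. Genes present in a fold-change table are called measured below, and the rule by which genes entered is not stated. In the deposited fold-change tables the fold changes against the control mean and the mean expression are log2 values. The deposited p-values are those of an F-test over all concentrations, with their Benjamini-Hochberg adjustment, and those of a lack-of-fit test of each gene's curve. The other deposited columns hold the F statistic, the residual SD of each curve and the benchmark doses, that is, the concentration at which a gene's fitted curve leaves the control by a set response, with lower and upper bounds (BMDL and BMDU). The column names and values match those that limma and FastBMD write, although the authors' tables do not name these tools. Methylmercury concentrations run from 0.25 to 250 in the tables and from 0.001 to 1 in the sample titles, a factor of 250 throughout, with no unit stated. They are given below on the table scale, and fluoxetine is given in ppb as in the titles.

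Because mean expression, fold changes, F and p were deposited together, the group means, the moderated residual variance and the SE of every fold change were recovered from them. Adjusted p-values recomputed from the deposited p-values differed from the deposited ones by at most 3.3e-15. For fluoxetine, 1 library per concentration meant that the recovered means were the libraries themselves. The distance between both controls was also recovered, but not which of them was higher. For methylmercury only the mean of each pair was recoverable, not the single libraries. The recovered values were log2 of counts with an offset of 0.5 and 1 scaling factor per library, and in the gill line 70.8% of back-transformed values between 0 and 50 lay within 0.05 of a whole number. Estimated reads in the tabulated genes ran from 7.75 M to 11.52 M for methylmercury, as 1 value per pair of libraries, and from 1.84 M to 7.68 M per library for fluoxetine. Where a group had 0 counts of a gene, the fold change of a named gene is given as a bound computed with 3 counts per library. List medians and the neighbouring run of genes use values without such bounds. Such bounds, and all depths, cover counting error only.

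Changed genes were those with the authors' own adjusted p under 0.05. No edgeR or DESeq2 fit was possible without counts. Directions are those at the highest concentration. The median gene fell with methylmercury, so methylmercury fold changes of single genes, and those of lists for both chemicals, are given relative to the median of all genes in the same line and concentration, with the recovered SE for single genes. Fluoxetine fold changes of single genes are against the control mean. Differences at single concentrations relative to the median, and the difference between lines, were tested with the recovered moderated variance and adjusted by the Benjamini-Hochberg method over the genes. Fluoxetine libraries were also fitted with limma 3.58.1 in R 4.3.3, as a trend on log10 of the concentration plus the smallest concentration, and as a trend on the concentration itself. The log10 form was fixed before the data were examined for the case that values per library could be had, and the linear form was added afterwards.

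Gene lists, 22 in number, were matched by gene symbol only, so the many trout genes known only by a locus number belong to none. They covered metal, oxidative, heat and unfolded protein stress, cholesterol and lipid metabolism, lysosome, monoamines, xenobiotics, cell cycle, apoptosis, tubulin, selenoproteins, proteasome, ribosomal proteins, inflammation, matrix, respiration and cell type markers. Each list was tested for the share of changed members with Fisher's exact test, two-sided, against all other tabulated genes, as 1 family of 125 tests. Direction was tested with camera from limma on the moderated statistics of lists with at least 3 members. A preset correlation of 0.01 was used, and the test was repeated with a correlation estimated from the fluoxetine residuals of the same line, also for methylmercury. Estimates came from the members in the fluoxetine table, and negative ones counted as no correlation. Where the estimate lay under the preset, the repeat was no stricter a test. Both forms were adjusted over all lists, lines and chemicals.

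Points of departure were the 20th lowest gene benchmark dose, the 10th percentile, and the first mode, that is, the lowest maximum of the kernel density of log10 benchmark doses holding at least 5% of genes. All used the genes that carried the authors' flag for passing every filter. Intervals of 95% came from 1000 resamplings of genes and cover gene sampling only, not the spread between libraries. Benchmark doses of the same gene in both lines of a pair were compared by flipping the signs of log10 ratios, two-sided, with 100000 permutations or exactly with fewer than 10 genes. The statistic tested was the mean log10 ratio, and medians are given as description. Overlap of changed genes was tested with Fisher's exact test. These tests run across genes, which are not independent replicates.

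Named genes were chosen by rule: the 5 highest and 5 lowest fold changes among changed genes with a symbol, the 5 lowest benchmark doses, up to 4 members of each list, and a fixed set of marker genes for each chemical. The comparisons, lists, naming rule and most alternative settings were fixed before the data were examined. A first run departed from them in the direction of the overlap, the test of benchmark doses and the family of list tests, and was corrected to them after its results had been seen. Added afterwards were the centring on the median gene, for list tests too, the linear trend, the test of signs alone, the fits of every gene model, and the fluoxetine fits without single concentrations. Computations used python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The recovery and the trend fits were tested on simulated data. In these, the F-test found 0 of 100 simulated fluoxetine changes of 4 log2 units in each line, whereas the log10 trend found 91, 85 and 91 in gill, liver and gut. The changes were simulated along the log10 scale that the trend fits, which favours the trend. No gene positions are given because the authors' genome build is not stated. The order of genes along the chromosome was taken from the USDA_OmykA_1.1 annotation by gene identifier.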

Results

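Gene expression was measured by RNA sequencing in trout cells from gill, liver and intestine after 24 h with methylmercury, an organic mercury compound, or fluoxetine, an antidepressant that blocks serotonin uptake. Each line had 12 methylmercury libraries, 2 for the control and 2 at each of 5 concentrations, and 11 fluoxetine libraries, 2 controls and 1 at each of 9 concentrations from 1.6 to 1000 ppb. The authors' deposited tables covered 22579, 23203 and 21859 genes for methylmercury and 22051, 23526 and 22401 genes for fluoxetine in gill, liver and gut. Estimated depth in the tabulated genes was 7.75 M to 11.52 M reads for methylmercury, as 1 value per pair of libraries, and 1.84 M to 7.68 M per fluoxetine library. The comparisons ask which genes changed with each chemical, at which concentrations, and how far the 3 lines responded alike.

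Methylmercury raised genes that protect cells from oxidative damage and misfolded protein in all 3 lines. At the highest concentration, hspa1b, an inducible Hsp70 chaperone, rose by 7.44 ± 0.91 log2 units relative to the median gene in gill, 7.88 ± 0.35 in liver and 9.31 ± 0.46 in gut (SE, n = 2 libraries per group). The heme-degrading enzyme gene hmox1a rose by 3.47 ± 0.14, 4.47 ± 0.58 and 3.04 ± 0.30. The gene for keap1a, the adaptor that targets Nrf2 for degradation, rose by 5.03 ± 0.18, 6.47 ± 0.20 and 6.54 ± 0.13, and chac1, which degrades glutathione and belongs to the integrated stress response, rose by 2.99 ± 0.09, 3.64 ± 0.23 and 4.18 ± 0.09. All of these passed the authors' F-test in each line, with the largest adjusted p at 0.0138 for hmox1a in liver.

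Of the list of oxidative stress and glutathione genes controlled by Nrf2, 14 of 15 measured members changed in gill, 12 of 12 in liver and 11 of 11 in gut. Adjusted over the list alone, the counts were also 14, 12 and 11. Relative to the median gene, 13, 11 and 11 of these were higher and 1, 1 and 0 lower, with medians of 2.96, 3.49 and 3.04 log2 units over all members. Examples were gclc, which encodes the catalytic subunit of the first enzyme of glutathione synthesis, at 4.23 ± 0.21 in gill and 4.43 ± 0.13 in liver, and the autophagy receptor gene sqstm1 at 5.95 ± 0.12 in gill. Of the heat shock list, 9 of 9, 11 of 12 and 6 of 6 members changed, with 8, 10 and 6 of them higher relative to the median gene and median changes of 5.77, 2.03 and 3.07. As deposited, 8, 9 and 3 were higher and 1, 2 and 3 lower. The co-chaperone gene bag3 rose by 6.40 ± 0.17 in gill and 5.56 ± 0.47 in liver. In camera, the Nrf2 list was higher in each line (adjusted p = 1.0e-10, 1.0e-10 and 4.6e-10), and so was the heat shock list (adjusted p = 5.2e-06, 1.0e-05 and 0.00316). The unfolded protein and integrated stress response list was higher in liver, where 9 of 12 members changed, and in gut, where 9 of 9 changed (adjusted p = 8.7e-04 and 4.3e-04). As deposited, 5 of these were higher and 4 lower in each line, and relative to the median gene 7 and 8 were higher. In gill 4 of its 5 members changed, and camera gave no call. All of these camera calls held with the estimated correlation. For Nrf2 in gill and heat shock in liver and gut that estimate lay under the preset 0.01, so the repeat was no stricter there.

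**Figure D1:**
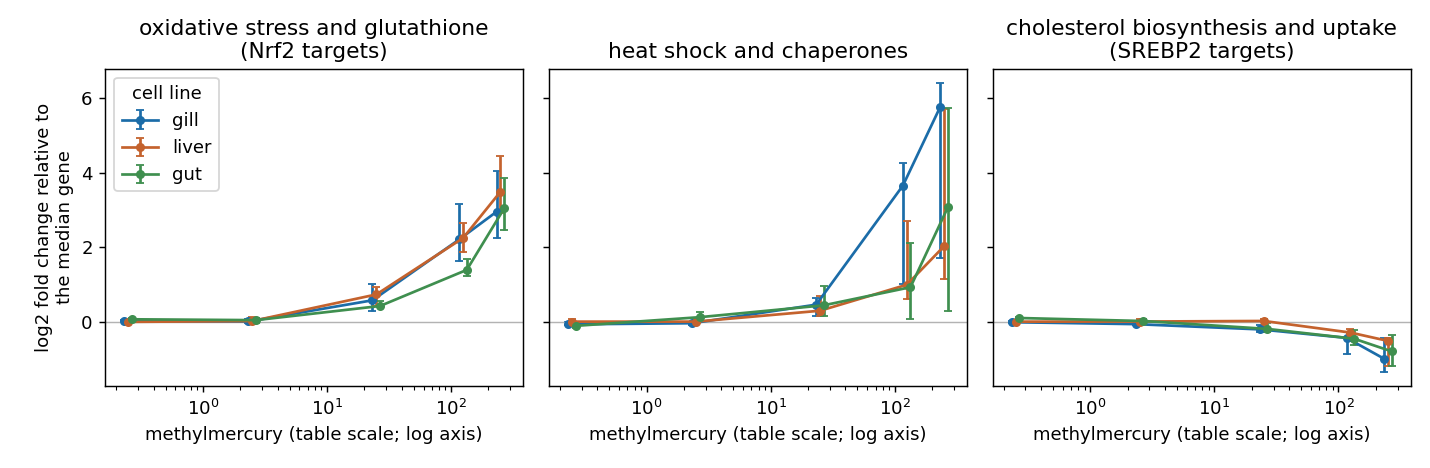
Median log2 fold change relative to the median gene for 3 gene lists (y axis) against methylmercury concentration on the table scale, which has no stated unit (log x axis), in the gill, liver and gut lines, drawn slightly apart along x. Bars span the quartiles of the list's members, not replicates, and at 250 the Nrf2 list stood at 2.96, 3.49 and 3.04.

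Most genes of cholesterol synthesis and uptake lay below the median gene. All 17 measured members in gill, 17 in liver and 18 in gut changed in the F-test without centring, and 10, 5 and 11 with centred fold changes. Of all members 15, 15 and 17 were lower than the median gene, with list medians of -0.98, -0.50 and -0.78. The gene of HMG-CoA reductase, hmgcra, whose product catalyses the rate-limiting step of cholesterol synthesis, stood at -1.39 ± 0.12 in gill and -1.30 ± 0.14 in liver. The sterol dehydrogenase gene nsdhl stood at -1.23 ± 0.19 in liver and -2.02 ± 0.13 in gut. In camera the list was lower in gut (adjusted p = 3.6e-04, and 1.3e-04 with an estimated correlation). In gill and liver the preset correlation gave adjusted p = 1.3e-04 and 3.3e-04, but the call was lost with an estimated correlation, at adjusted p = 0.248 and 0.492. The gut estimate of -0.05, from the 5 members in the fluoxetine table, was no stricter than the preset. Those of gill and liver were 0.39 and 0.73, so the repeat does not set gut apart from them. The beta-tubulin gene tubb2b, whose product forms microtubules, stood at -2.13 ± 0.09, -1.35 ± 0.11 and -1.99 ± 0.09 in gill, liver and gut.

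Of the respiratory chain list, 27 of 27, 14 of 16 and 29 of 30 members changed. Relative to the median gene these fell on both sides in gill (14 higher, 13 lower) and liver (7 and 7), with list medians of 0.02 and 0.06 and means of -0.09 and -0.09. In gut 3 were higher and 26 lower, with a median of -0.33, among them sdhaf3, an assembly factor of succinate dehydrogenase, at -1.18 ± 0.10. Camera gave adjusted p = 0.0039 for the lower values in gut, and adjusted p = 0.218 with an estimated correlation. By Fisher's exact test, 9 of the 125 list tests held more changed members than other genes did. These were the Nrf2 list in gill and liver (adjusted p = 0.0451 and 0.0021), heat shock in liver (0.0301), cholesterol in all lines (0.0021, 1.0e-04 and 0.00701) and the respiratory chain in all lines (4.0e-05, 0.0134 and 0.00124). These counts use the F-test without centring. With centred fold changes 5 tests passed, Nrf2 in gill, liver and gut (2.1e-04, 1.5e-05 and 0.00119) and heat shock in gill and liver (4.1e-04 and 0.00119). The cholesterol calls were then lost (0.172, 1 and 0.991, with 10 of 17, 5 of 17 and 11 of 18 changed), and so were those of the respiratory chain (0.678, 1 and 1, with 3 of 27, 1 of 16 and 11 of 30). Without centring the next was p53 and apoptosis in liver at 0.0524, with 7 of 7 members changed, 3 higher and 4 lower on either scale, and a median of -0.02 relative to the median gene (camera adjusted p = 0.492). Among them the growth arrest gene gadd45ab stood at 3.34 ± 0.31 and the sestrin gene sesn1 at -0.88 ± 0.38.

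Inflammation and matrix genes rose in the gut line. Of 6 measured genes of the inflammation list 4 changed there, all higher, including socs3, a feedback inhibitor of cytokine signalling, at 5.21 ± 0.13 and the NF-kappa-B inhibitor gene nfkbiab at 3.71 ± 0.11. Camera gave adjusted p = 0.00575, and 0.00757 with an estimated correlation, which was negative (-0.11) and so no stricter than the preset. Of the matrix list 7 of 9 changed in gut, 6 of them higher, including mmp9, a secreted protease, at 6.79 ± 0.31 (camera adjusted p = 0.00106, held with an estimated correlation). In gill 6 of 8 matrix genes changed, all lower as deposited and 2 higher and 4 lower relative to the median gene, with a list median of -0.59. In liver 2 of 13 changed, both lower on either scale, and camera called neither line (adjusted p = 0.415 and 0.904). In gill 2 of 8 and in liver 3 of 6 inflammation genes changed, with socs3 at 2.74 ± 0.18 and 3.40 ± 0.24, and camera gave no call (adjusted p = 0.0857 and 0.128). The others were higher as well, except stat1b in liver, at -0.73 as deposited and 0.05 ± 0.14 relative to the median gene. The chemokine gene ccl19a.1 rose by 8.98 ± 0.95 in gill and 7.94 ± 0.36 in gut. Difference between lines was not tested for these lists.

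Metal-binding and xenobiotic genes differed in direction from gene to gene. Metallothionein mt2, which binds metal ions, rose by 2.94 ± 0.26 in gill and was not in the gut table. In liver it stood at 1.14 ± 0.25 relative to the median gene and at 0.36 as deposited. The F-test, which takes values as deposited, gave mt2 in liver an adjusted p of 0.524. With centred fold changes 2 of the 3 liver metal genes changed, and the centred result of mt2 alone is not given here. The gene of the conjugate transporter abcc2 rose by 4.71 ± 0.14, 5.62 ± 0.13 and 4.62 ± 0.12. Values of the aryl hydrocarbon receptor target cyp1a3 were -1.33 ± 0.33 in liver and -3.75 ± 0.27 in gut, whose F-tests passed. Of the xenobiotic list 3 of 8, 7 of 12 and 7 of 8 members changed, of the metal list 4 of 5, 0 of 3 and 2 of 2, of the lysosome list 12 of 13, 3 of 4 and 12 of 13, and of the selenoproteins 8 of 9, 6 of 8 and 9 of 10. Selenoprotein gene selenoh stood at -0.92 ± 0.12, -1.05 ± 0.14 and -1.81 ± 0.15. Of the cell cycle list 7 of 8, 5 of 6 and 2 of 2 changed, of the lipid list 9 of 11, 8 of 10 and 7 of 10, and of the p53 and apoptosis list 3 of 5, 7 of 7 and 5 of 5. Of the tubulin list 3 of 3, 1 of 3 and 3 of 4 changed, and of the monoamine list 1 of 4, 0 of 3 and 1 of 4. These counts use the F-test without centring, which called 56.8%, 45.8% and 63.4% of all genes. With centred fold changes 3, 1 and 5 xenobiotic, 3, 2 and 2 metal and 3, 0 and 4 lysosome genes changed. So did 3, 3 and 8 selenoprotein, 3, 0 and 2 cell cycle and 2, 3 and 3 lipid genes. For p53 and apoptosis, tubulin and monoamines the numbers were 3, 3 and 3, then 1, 1 and 2, then 0, 0 and 1. The only measured proteasome member, psmd1, rose by 1.52 ± 0.09, 1.64 ± 0.11 and 1.85 ± 0.07, and 1 of 2 ribosomal protein genes changed in liver, the only line that had any.

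Cell type markers were counted as well, of which the hepatocyte list is no other cell type's for the liver line, nor the epithelial list for the gut line. Of the leukocyte markers 0 of 1, 0 of 2 and 0 of 2 changed in gill, liver and gut, of the epithelial markers 1 of 5, 1 of 5 and 0 of 3, of the endothelial and erythroid markers 1 of 3, 2 of 4 and 0 of 2, and of the hepatocyte markers 0 of 1, 1 of 3 and 2 of 4. These counts, too, come from the F-test without centring. Transferrin, tf, made by hepatocytes, stood at -1.16 ± 0.22 in liver. The fibrinogen gene fga stood at 2.15 ± 0.22 in gut.

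Across all genes, the authors' F-test called 12826 genes in gill (56.8%), 10616 in liver (45.8%) and 13852 in gut (63.4%). As deposited, 2318, 1747 and 2436 of these were higher at the highest concentration and 10508, 8869 and 11416 lower. The median gene itself stood at -0.89, -0.78 and -1.01 log2 units there, at -0.46, -0.43 and -0.56 at 125, and at -0.05, -0.11 and -0.21 at 25. Relative to that shift 4330, 2972 and 4923 called genes were higher and 8496, 7643 and 8928 lower. These are genes called without centring, a choice that favours genes that fell. With each concentration centred on its median gene, the F-test called 6272, 4422 and 8851 genes. Relative to the median, 5, 8 and 12 genes differed from control at 0.25 in gill, liver and gut, 8, 10 and 11 at 2.5, 84, 16 and 216 at 25, 3716, 2499 and 3519 at 125, and 8266, 6719 and 10445 at 250. Of those at 250, 3831, 3634 and 4778 were higher and 4435, 3085 and 5667 lower than the median gene.

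**Figure D2:**
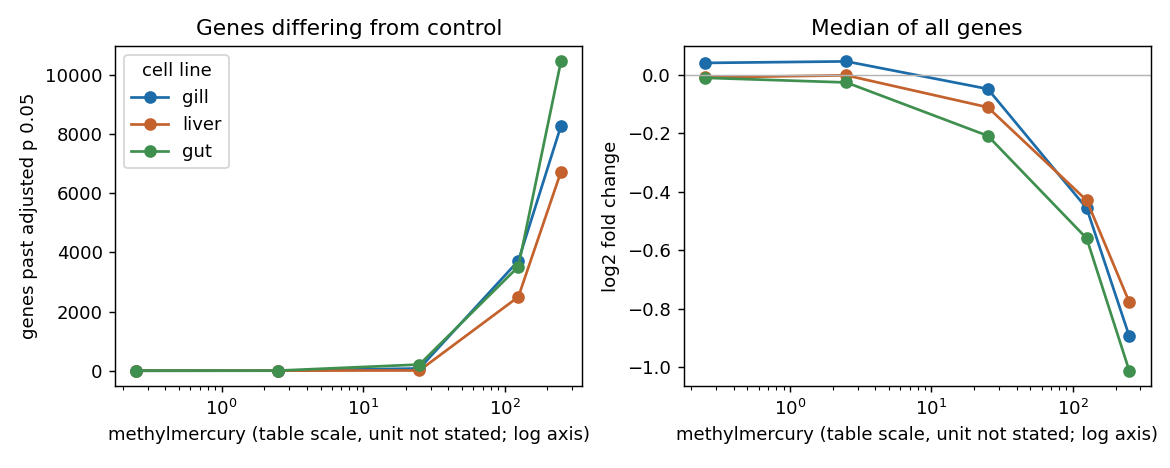
Genes differing from control relative to the median gene at adjusted p under 0.05 (left y axis) and the median log2 fold change of all genes (right y axis) against methylmercury concentration on the table scale, unit not stated (log x axes), for the 3 lines. Counts rose from 5, 8 and 12 at 0.25 to 8266, 6719 and 10445 at 250, while the median fell to -0.89, -0.78 and -1.01.

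Some genes had no counts left at the highest concentration, or none in the control. The lowest deposited fold changes belonged to cep78 and c2cd5 in gill, traf2a and asap2a in liver, and nfat5a and nisch in gut, all with 0 counts at 250. With 3 counts as the floor per library, their log2 changes as deposited lay at or below -5.38, -5.25, -5.08, -4.18, -5.57 and -5.24. In liver stk31 had 0 counts in the control and lay at least 7.96 log2 units higher at 250. Such zero counts at this depth do not show absence of the transcript.

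The 3 lines shared much of the response. In all of them 12586 genes were measured and 4939 changed, 434 higher and 4397 lower as deposited, or 517 higher and 3408 lower relative to the median gene. These directions, like those of the pairs below, were counted over genes called without centring, which favours genes that fell. Of genes changed in both lines of a pair, as deposited 154 of 6307 (2.44%) went opposite ways in gill and liver, 315 of 7865 (4.01%) in gill and gut, and 241 of 6881 (3.50%) in liver and gut. Shared higher genes numbered 764, 760 and 686 for these pairs, 6.93, 5.54 and 5.92 times the number independence would give. Shared lower genes numbered 5389, 6790 and 5954, 1.69, 1.57 and 1.63 times that number. Relative to the median gene the ratios were 3.30, 2.62 and 2.65 for higher and 1.79, 1.70 and 1.76 for lower genes, and 14.9%, 17.0% and 17.9% went opposite ways. The tests were Fisher's exact tests across genes, which are not independent replicates, and the p-values for the genes as deposited were too small to be represented.

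A run of neighbouring genes stood above the median gene, singled out after the values were seen. Behind aldh16a1 on the chromosome, 26 measured genes in a row stood over 1 log2 unit above the median gene at 250 in gill and 22 in liver, and 18 in gut, where LOC118937701 at -0.60 broke the series. The median of the measured genes of this region was 2.73, 4.28 and 3.44, and 21 of 26, 19 of 22 and 19 of 23 of them passed the F-test. They carried 8.89%, 1.56% and 5.25% of all counts in the control and 23.9%, 16.0% and 23.2% at 250. LOC118936428 alone went from 2.52% to 6.24%, from 0.405% to 4.31% and from 2.52% to 11.2% of counts. Most of these genes carried a locus number only, so what they encode is left open.

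**Figure D3:**
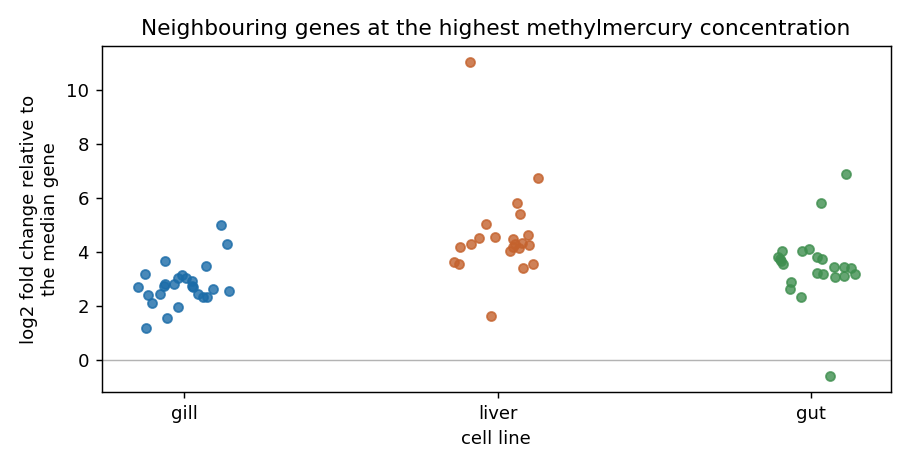
Log2 fold change relative to the median gene at the highest methylmercury concentration (y axis) for each measured gene of the neighbouring run in the gill, liver and gut lines (x axis); each point is a gene. All points but LOC118937701 in gut lie above 1, and medians were 2.73, 4.28 and 3.44.

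For benchmark doses of methylmercury, keap1a had a low value in each line, 1.72 in gill, 0.922 in liver and 0.418 in gut on the table scale. The lowest among genes with a symbol were foxo1a, a transcription factor of stress and metabolism, at 0.0316 in gill, odad4 at 0.0287 in liver and phldb1a at 0.109 in gut, all under the lowest tested concentration of 0.25. In gut cdh2, which encodes N-cadherin, followed at 0.314 and mmp9 at 0.440. Of the genes that entered, 20.3%, 19.6% and 15.9% had rising curves.

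The 20th lowest gene lay at 1.15 (95% interval from resampling genes 0.503 to 1.47) in gill, 0.960 (0.438 to 1.44) in liver and 0.449 (0.346 to 0.553) in gut. The 10th percentile lay at 7.86 (7.49 to 8.18), 8.57 (7.91 to 9.12) and 5.50 (5.18 to 5.80). The first mode lay at 24.3 (17.0 to 26), 34.0 (22.4 to 36.8) and 25.4 (2.39 to 29.8). These rest on 4821, 3482 and 6224 genes, and intervals do not cover the spread between libraries. Other settings moved them, as given below. A narrower bandwidth lowered the first mode in liver and gut, and with every gene model the 20th gene was no longer lowest in gut. In genes with a value in both lines, gill lay below liver with a median ratio of 0.780 over 1504 genes. Liver lay above gut with a median ratio of 1.25 over 1552 genes. For both pairs sign-flip permutation of the mean log10 ratio gave adjusted p = 3.0e-05, where 1e-05 was the smallest raw p it can give. Gill and gut had a median ratio of 0.907 over 2319 genes. Their mean log10 ratio was -0.0138, against a median of -0.0426, and the permutation of the mean gave adjusted p = 0.438. A test of signs alone, added later, passed at adjusted p = 2.6e-04. For 1375, 1073 and 1426 genes with straight-line curves, centring each concentration on its median gene moved the median benchmark dose from 27.2 to 44.3, from 33.7 to 50.1 and from 27.8 to 49.1.

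**Figure D4:**
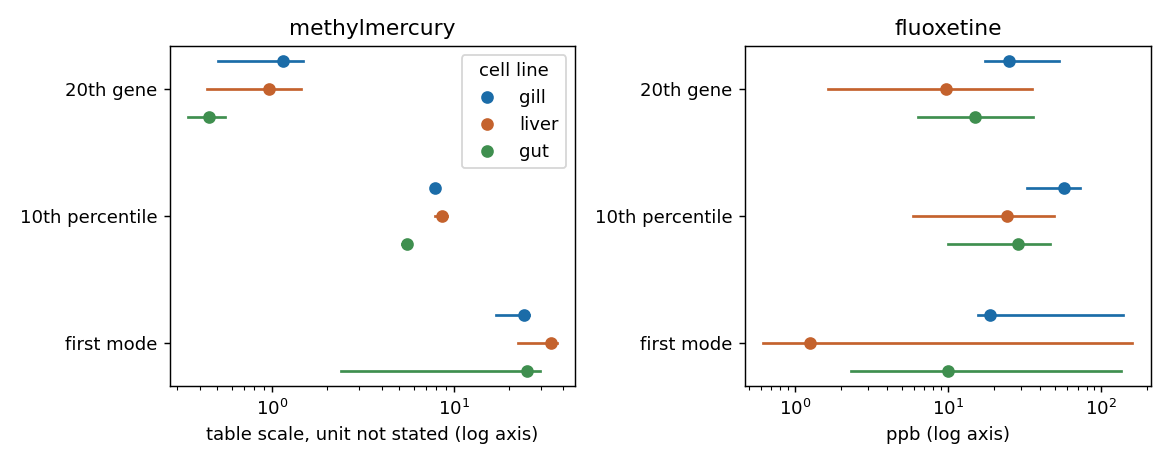
Points of departure by line for methylmercury on the table scale, unit not stated (left), and fluoxetine in ppb (right), on log x axes; points are values and bars 95% intervals from resampling genes. The 20th gene for methylmercury lay at 1.15, 0.960 and 0.449 in gill, liver and gut.

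Fluoxetine gave no gene past the authors' F-test in any line. In the gill line the Nrf2 list was higher along the log10 concentration (camera on limma statistics, adjusted p = 9.3e-04, and 0.00143 with an estimated correlation), with 4 of 7 members at an unadjusted trend p under 0.05 and medians of 0.18 log2 units at 500 ppb and 0.09 at 1000 ppb relative to the median gene. Its member keap1a stood at 0.67 log2 units against the control mean at 1000 ppb, with a trend adjusted p of 0.872. This call stayed past the threshold without each concentration in turn, with adjusted p between 9.0e-04 and 0.00964. Its estimated correlation was 0.0067, under the preset, so that repeat was no stricter. Camera takes the genes of a list as its units. Over the 10 points, control included, the median of the members correlated with log10 concentration at Pearson's r = 0.67. That test did not pass (permutation p = 0.0324, adjusted over 51 tests 0.186, and 0.265 on the linear concentration). Camera gave no call for this list in liver and gut (adjusted p = 0.972 and 0.335), where its medians at 1000 ppb were 0.05 and -0.06, and the difference between lines was not tested.

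Camera also called the lysosome list in gut and liver and the stress response and lipid lists in liver, higher in each case, and with an estimated correlation each of these 4 calls was lost without the 1000 ppb library. For the lysosome list camera gave adjusted p = 2.3e-05 in gut and 0.0026 in liver, and 0.0376 in each with an estimated correlation. Median changes at 1000 ppb relative to the median gene were 0.28 over 9 members in gut and 0.11 over 10 in liver. The unfolded protein and integrated stress response list in liver had a median of 0.29 over 7 members (adjusted p = 3.3e-04, and 0.00646 estimated), and the lipid list in liver 0.40 over 10 members (adjusted p = 0.00575, and 0.0380 estimated). Selenoproteins in gut had a median of 0.07 (adjusted p = 0.0321, and 0.0376 estimated). That estimate was negative (-0.02) and so no stricter than the preset. The matrix list in gill, lower with a median of -0.43 over 8 members, lost its call (adjusted p = 0.0321, and 0.120 with an estimated correlation). Without the 1000 ppb library the preset correlation gave adjusted p = 0.148 for lipids and 0.0548 for the lysosome in liver, 0.0548 for gut selenoproteins and 0.152 for gill matrix. The stress response list in liver and the lysosome list in gut then gave 0.0158 each, and 0.0967 and 0.289 with an estimated correlation. Selenoproteins also lost the call without 1.6, 200 or 500 ppb (0.114, 0.122 and 0.0670) and gill matrix without 200 ppb (0.118). With an estimated correlation the liver lysosome call was lost without 1.6, 8, 100, 200, 500 or 1000 ppb (0.0649, 0.0560, 0.0610, 0.0536, 0.0538 and 0.216) and the gut lysosome call also without 1.6 or 500 ppb (0.0930 and 0.0837). The liver lipid call was then lost without 8, 500 or 1000 ppb (0.0560, 0.0837 and 0.289), and the selenoprotein call without 1.6, 200, 500 or 1000 ppb (0.115, 0.129, 0.0783 and 0.0640).

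Among the fixed fluoxetine markers, insig1, which holds back sterol synthesis, stood at 0.88 log2 units against the control mean in liver and 0.49 in gut at 1000 ppb, hmgcra at 0.25 in gill and 0.22 in liver, and cyp1a3 at 2.30 in gut and 0.92 in liver. The serotonin transporter gene slc6a4b stood at -0.06, 0.45 and -0.58. The log10 trend passed for none of these. The linear trend, added afterwards, passed for insig1 in liver and gut and for cyp1a3 in gut (limma adjusted p = 0.00469, 0.0305 and 0.00439). Chance is not excluded for the linear calls in gut, as given below. The serotonin and monoamine list stood at medians of -0.28, 0.31 and -1.06 relative to the median gene over 4, 5 and 3 members at 1000 ppb in gill, liver and gut, without a camera call (adjusted p = 0.0605, lower, 0.490 and 0.358). Marker lists of 2 members reached medians of 1.37 in gill, for endothelial and erythroid cells, and of -1.13 in liver and 1.85 in gut, for leukocytes, each from single libraries. In the F-test adjusted over the list alone, 4 of 5 hepatocyte markers and 2 of 4 epithelial markers passed in gut and 2 of 6 xenobiotic genes in gill, and other lists had at most 1. With 1 library per concentration, these values have no replicate.

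In the F-test 0 genes passed in each line, with smallest adjusted p-values of 0.226, 0.320 and 0.321. At an unadjusted p under 0.05 there were 2528, 2454 and 2253 genes, where a calibrated test without any effect would give 1103, 1176 and 1120. Only 1 residual degree of freedom, the distance between both controls, was available beside the moderation. Calibration was not tested, so the excess alone does not show effects. The log10 trend in limma also called 0 genes in each line, with 1203, 1515 and 1471 at an unadjusted p under 0.05, although without the 100 ppb library it called 1 gene in gut (adjusted p = 0.0494). A linear trend called 2 genes in gill (0 higher, 2 lower), 29 in liver (14 higher, 15 lower) and 36 in gut (15 higher, 21 lower). Without the 1000 ppb library the linear counts were 0, 54 and 1, of which 8 in liver were among the 29, and without 500 ppb they were 114, 87 and 66. In gut they were 6 without 1.6 ppb, 3 without 4, 8, 20, 40 or 100 ppb, and 20 without 200 ppb. In gill they were 0 without 8 ppb.

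Liver and gut shared 7 of the genes called by the linear trend, all higher in both, where independence would give 0.0537. They were insig1, proca1, LOC110501969, LOC110535597, LOC110525169, LOC110497995 and LOC110500176, of which proca1 and the locus numbers were picked out after their values were seen. From 500 to 1000 ppb insig1 went from 0.59 to 0.88 in liver and from 0.31 to 0.49 in gut, and proca1 from 0.83 to 1.30 and from 0.81 to 1.04. Leaving out a concentration in both lines left 0 shared calls for 1.6, 4, 8, 20, 40, 100 and 1000 ppb, 3 for 200 ppb and 7 for 500 ppb. The slopes of all 7 stayed positive each time, an outcome that picking genes with positive slopes favours.

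**Figure D5:**
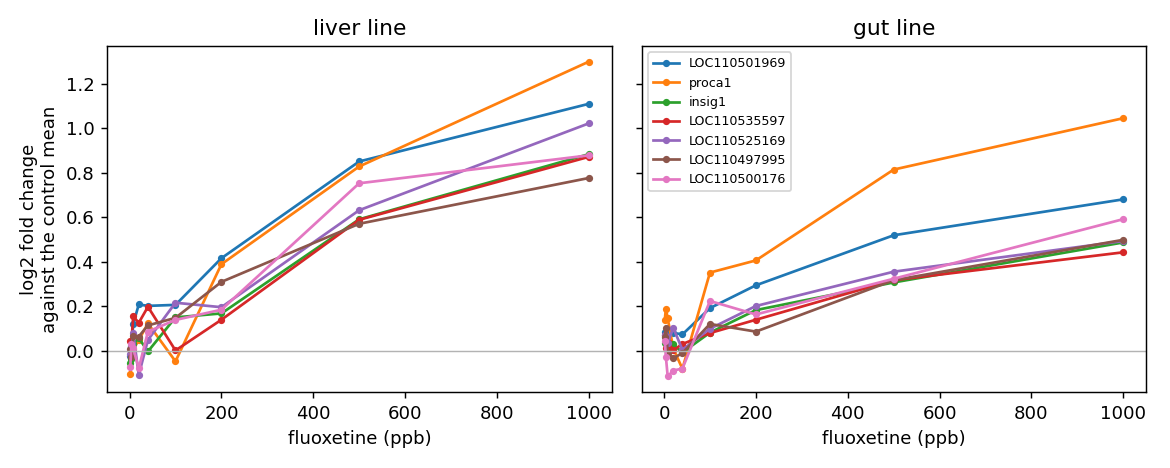
Log2 fold change against the control mean (y axis) of the 7 genes with a linear fluoxetine trend in both liver and gut, by concentration in ppb (linear x axis); each point is 1 library. At 1000 ppb insig1 stood at 0.88 in liver and 0.49 in gut.

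Fluoxetine benchmark doses came from 332, 244 and 247 genes that passed on unadjusted p-values only, with the largest adjusted p at 0.435, 0.479 and 0.496. The lowest among genes with a symbol were the glutamate receptor gene grm3 at 9.02 ppb in gill, mapta, which encodes the microtubule protein tau, at 0.665 ppb in liver, and marveld1 at 0.382 ppb in gut. The values of mapta and marveld1 lay under the lowest tested concentration of 1.6 ppb. The 20th gene lay at 24.8 ppb (17.4 to 53.2), 9.67 (1.65 to 35.3) and 14.9 (6.33 to 35.8), and the 10th percentile at 57.4 (32.8 to 72.8), 24.4 (5.88 to 49.2) and 28.7 (9.96 to 46.5). The first mode lay at 18.8 (15.8 to 139), 1.25 (0.623 to 159) and 9.96 (2.33 to 135). A stricter lack-of-fit limit moved the 20th gene above its interval in each line, as given below. Gill and liver shared 4 of these genes, gill and gut 5, and liver and gut 5, of which 0, 0 and 3 went opposite ways. Those lower in both numbered 4, 5 and 2, where independence would give 1.24, 1.08 and 0.876 (Fisher's exact test across genes, p = 0.0362, 0.00462 and 0.219, adjusted over 6 tests 0.109, 0.0277 and 0.437), and none was higher in both. Exact sign flips of their ratios gave adjusted p = 0.875, 0.875 and 0.656, where the smallest p that 4 or 5 genes allow is 0.125 or 0.0625, so that this test could not pass.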

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

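The tests of genes moving opposite ways in a pair of lines were chosen after the data had been seen, while the comparison of benchmark doses was set before. The genes named here were picked out after their values were seen.

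Deposited benchmark doses of the same genes for methylmercury differed between cell lines. The median log10 ratio of benchmark doses was -0.11 for gill over liver, with 933 of 1504 genes lower in gill, and 0.0986 for liver over gut, with 896 of 1552 genes lower in gut. Sign-flip permutation across genes of the mean log10 ratio, which was -0.106 and 0.133, gave both an adjusted p of 3.0e-05. These genes share libraries, so the test covers the sampling of genes and not the spread between cultures. The doses rest on fold changes that hold the shift of the median gene. Centring moved the medians of straight-line genes from 27.2, 33.7 and 27.8 to 44.3, 50.1 and 49.1 in gill, liver and gut, which left liver and gut close, and the comparison between lines was not repeated on centred values.

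Some genes moved in opposite directions relative to the median gene at the highest methylmercury concentration. By a test of the difference, 909 of 16083 genes differed between gill and liver, 1768 of 15741 between gill and gut and 2004 of 16115 between liver and gut. Among them 89, 185 and 145 passed in both lines with opposite signs. The cell cycle inhibitor gene cdkn1a stood at -0.37 ± 0.09 in gill, 1.53 ± 0.22 in liver and -2.17 ± 0.11 in gut (SE, n = 2 libraries per group; limma-type moderated difference, adjusted p = 0.0114 for gill against liver and 8.9e-04 for liver against gut). The phosphatidate phosphatase gene lpin1 stood at -0.67 ± 0.21 in gill and 2.10 ± 0.17 in liver, and the cytochrome gene cyp1b1 at 3.28 ± 0.68 and -1.30 ± 0.32. The kinase gene cdk14 stood at 1.47 ± 0.40 in gill, and had 0 counts at 250 in gut. As deposited, cdkn1a was higher than control in liver and lower in gill and gut. The scale of each line's shift affects such signs, since the medians removed were -0.89, -0.78 and -1.01.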

How the results depend on the processing

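Of the alternatives to results that answer a comparison, 176 kept the result, 61 moved it, 1 took a test past its threshold, and none reversed a direction. Kept means a count within 1.5 times, a point of departure within its interval from resampling genes, or a test on the same side. Every overlap ratio for methylmercury stayed above 1 with its test passed. The number of list tests passed was 9, and 8 with exact symbols, 7 with 1 gene per symbol stem and 11 at adjusted p under 0.01, without a comparison of which lists, and 5 with centred fold changes, where those of cholesterol and the respiratory chain were lost. The log10 trend called 0 genes, except 1 in gut without 100 ppb. For single genes and fluoxetine calls of lists and trends, 110 were kept, 30 moved and 8 lost a call. Where an alternative is a stricter or looser limit, fewer or more genes follow from its construction, and elsewhere the cause was not tested. Settings chosen after the data were seen were the centring, both limma trends as run on recovered libraries, the fits without single concentrations, every gene model and the test of signs alone. No paired analysis was possible because the deposited tables hold only group means for methylmercury, and fluoxetine had 1 library per concentration. For the same reason, leaving out each methylmercury replicate and using the ctrl or the H2O control alone were not run. Without counts, neither were another normalization of libraries, low-count filter or pseudocount. Run instead were the centring on the median gene and a limit to genes at or above the median expression. Limiting fluoxetine benchmark doses to adjusted p under 0.05 left no genes. Changed genes for methylmercury numbered 8380 in gill and 4600 in liver at unadjusted p under 0.001, 6468 in liver at adjusted p under 0.01, and 6272, 4422 and 8851 when centred. For fluoxetine they numbered 24, 13 and 16 at unadjusted p under 0.001 and 2, 29 and 36 with the linear trend, whose leave-one-out range was 0 to 114, 17 to 87 and 1 to 66, and which numbered 5, 38 and 34 when centred. Genes with an absolute log2 change of at least 1 at the highest concentration numbered 13403, 11603 and 14150 for methylmercury and 3089, 2752 and 2399 for fluoxetine. At a limit of 2 they numbered 4176, 3516 and 5231, and 1179, 1113 and 888. At 0.58 they numbered 17602 for methylmercury in liver and 5760, 4938 and 4286 for fluoxetine, and among changed genes alone 7149 for methylmercury in liver.

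With BMDL in place of the benchmark dose, the 20th gene for methylmercury lay at 0.243, 0.174 and 0.0834, the 10th percentile at 3.26, 2.87 and 1.59, and the first mode at 10.4, 13.2 and 2.23. For fluoxetine the 20th gene lay at 6.11 in gill and 4.78 in gut, the 10th percentile at 21.7 and 8.18, and the first mode at 4.73 and 1.73. With every gene model the 20th gene lay at 0.157, 0.185 and 0.168 for methylmercury and at 13.6 in gill and 4.24 in gut for fluoxetine, and the 10th percentile for methylmercury at 7.79 in liver and 4.83 in gut. The 5th percentile lay at 5.12, 5.31 and 2.85 for methylmercury and 20.9, 1.87 and 6.63 for fluoxetine. With a lack-of-fit p above 0.3 the fluoxetine 20th gene lay at 72.8, 64.6 and 51.2, and the 10th percentile in liver at 1.95. Without extrapolated values these lay at 40.1 and 51.3 in liver. Bandwidth moved the first mode to 7.03 for methylmercury in liver when narrowed to 0.5 times, and to 518.9 in gill and 245.5 in gut for fluoxetine when widened to 2 times. Wide intervals also covered moves of over 1.5 times. The first mode went to 4.17 for methylmercury in gut with the narrower bandwidth, to 146.2 without extrapolation and 153.7 with every gene model for fluoxetine in liver, and to 123.1 with every gene model and 4.27 with lack-of-fit p above 0.3 in gut. The fluoxetine 20th gene in liver went to 2.42 with BMDL, 2.52 with every gene model and 24.3 as the 25th gene, the 10th percentile in liver to 7.998 with BMDL, and the 20th gene in gut to 25.8 without extrapolation and 28.4 as the 25th gene. The gill to gut comparison of methylmercury benchmark doses, at a median log10 ratio of -0.0426, passed on signs alone (adjusted p = 2.6e-04). It did not pass with BMDL (0.190) or in the fixed test, which takes the mean log10 ratio (0.438). A fluoxetine library held as few as 1.84 M reads. In data simulated with the recovered variance the fluoxetine F-test found 0 of 100 changes of 4 log2 units in each line and the log10 trend 91, 85 and 91 with the same noise, and depth and the lack of replicates were not separated. For 2 log2 units the log10 trend found 64, 72 and 75, and the methylmercury F-test 36, 33 and 49, or 7, 0 and 12 for 1 log2 unit. These are unlike simulations, so their shares cannot be compared. Fluoxetine changes ran along the log10 scale that the trend fits, and methylmercury changes lay at the highest concentration only. With only 100 changed genes of each size, the adjusted threshold was also stricter than in the real methylmercury data. Over both sizes the log10 trend made 6, 12 and 11 false calls and the methylmercury F-test 7, 1 and 6.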

Other observations

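The tests below were chosen after the result was seen, except the check of the neighbouring run under fluoxetine. The bounds by which the test with 500 genes was judged were reset after its values were known.

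Further single genes named by the fixed rule had these values at 250 methylmercury. The gene of thrombospondin 4, thbs4a, rose by 8.79 ± 0.68 log2 units relative to the median gene in gill (SE, n = 2 libraries per group), and that of the bicarbonate transporter slc4a5a rose by 8.11 ± 0.44 in liver. The fatty acid receptor gene pparab stood at -2.41 ± 0.33 in liver. The mitotic checkpoint kinase gene bub1 stood at -0.62 ± 0.09, -1.91 ± 0.45 and -2.52 ± 0.22 in gill, liver and gut. The stress-responsive kinase gene plk3 rose by 2.39 ± 0.30 in liver and 2.26 ± 0.10 in gut. No shared function follows from them, as camera called neither the lipid list (adjusted p = 0.969, 0.785 and 0.951) nor the cell cycle list in gill and liver (0.216 and 0.704).

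Most genes fell at the highest methylmercury concentration, with the median at -0.89, -0.78 and -1.01 log2 units in gill, liver and gut. A candidate explanation is that a group of abundant, raised transcripts took up counts, since the 500 genes with the most counts at 250 held 40.1%, 43.0% and 32.5% of counts in the control and 72.1%, 64.9% and 72.2% at 250. Leaving out only the 10 most abundant genes left the median at -0.70 in the line with the smallest fall, which argues against so few genes as the cause. Leaving out the 500 brought it to -0.0538, -0.19 and -0.00906 in gill, liver and gut, but genes picked by their counts at 250 and a total then set equal favour a median near 0, so this decides nothing. The shares cannot say whether abundant transcripts rose or the others were lost per cell, and no biological explanation was tested because no external scale was available.

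The neighbouring run of raised genes may come from a shared response to methylmercury of genes that lie together. In 1000 shuffles of gene order in each line, runs reached at most 13, 11 and 12 genes against 26, 22 and 18, so that chance order is argued against at a permutation p of 0.001, the smallest that number of shuffles can give. Reads moved among the members would leave their sum in place, but genes of the run found in 1 line, summed in each other line, rose by at least 2.57 log2 units relative to the median gene, which argues against that. At 1000 ppb fluoxetine the largest median over lines was 0.11, so the genes covered did not rise as a set with fluoxetine. Since fluoxetine gave no gene past the F-test, this cannot tell a response to methylmercury from one to any exposure that changes expression. The fluoxetine tables held only 9, 9 and 16 of the genes. LOC118936428 was in none of them, although it held 2.52% of control counts in gill and in gut for methylmercury. Absence from these tables thus need not mean low expression. Still open is that reads of 1 raised copy were assigned to near-identical copies, since sequences of reads were not available.

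Genes with a linear fluoxetine trend numbered 2, 29 and 36, on a scale added after the log10 scale had given none, and a candidate explanation is chance in the order of single libraries. Of 100 concentration orders, the real one included, 67 gave as many calls in gill, 4 in liver and 5 in gut, with the highest other at 128, 88 and 45, so chance is not excluded in gill and gut, and in liver only before adjustment over 3 lines and by a bound set afterwards. For the genes shared by liver and gut, 7 in number, 1 of 100 orders of either line gave as many, the real one, and the highest other gave 1. That argues against chance order on this scale, at the smallest share 100 orders can give. It covers neither the choice of scale and overlap after the data were seen nor the weight of the single 1000 ppb libraries. Chance is therefore not excluded for the shared genes. Libraries with 0 counts of a gene may drive single calls. Such genes were 34.5% of the calls in liver (95% exact binomial interval 17.9 to 54.3) and 30.6% in gut (16.3 to 48.1). All of them fell, 10 of the 15 falling calls in liver and 11 of the 21 in gut. This leaves the explanation open for falling calls, while no rising call had 0 counts at a tested concentration. Both calls in gill and, without 500 ppb, 71 of 114, 53 of 87 and 43 of 66 calls were of such genes. Orders that gave 128 or 88 calls, where the median over other orders was 4, 7 and 3, point to some structure among single libraries, which was not traced, and handling shared by both lines at a concentration was not tested.

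Scores of lists under fluoxetine, the median change of their members at each of 10 points, were correlated with log10 concentration in 51 tests of a list in a line. None passed after adjustment over the 51, the smallest adjusted p being 0.0683. For the unfolded protein and integrated stress response list in liver, Pearson's r was 0.83 (permutation p = 0.00268) and Spearman's rho 0.745 (permutation p = 0.0173, adjusted 0.199), and r was 0.74 without the 2 points farthest from the median concentration. For the lysosome in gut r was 0.80 (permutation p = 0.00201) and rho 0.624 (permutation p = 0.0597), with r of 0.84 without those points. Falling lists in gill were matrix at r = -0.75 (permutation p = 0.0085) and monoamines at r = -0.73 (permutation p = 0.0165). On the linear concentration 4 tests passed, the smallest adjusted p being 0.0185. They were matrix in gill (r = -0.89), the stress response list (0.84) and lipids (0.94) in liver, and the lysosome in gut (0.95). With the mean of members in place of the median, on log10 concentration, none passed, the smallest adjusted p being 0.155.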
